A study of Mus musculus with 4 samples.

How the data were processed

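Gene expression was measured in 4 samples of mouse lineage-negative bone marrow cells, which are marrow cells depleted of cells carrying markers of mature blood lineages. Per the labels, 2 samples carried FLT3-ITD, an internal tandem duplication of the receptor tyrosine kinase FLT3 found in acute myeloid leukaemia, and had signalled for 48 h. The other 2 carried the empty vector pMIG. Samples were assigned to groups by their titles, which also give a replicate number and mark all 4 samples WT (wild type). Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

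Per the labels' protocols, RNA was extracted with a microprep kit, checked on a Bioanalyzer, converted to biotinylated cRNA and hybridised to Illumina bead arrays. The authors deposited a non-normalized intensity for each of 26512 probes on each array. Scanner software and background handling are not given in the sources used here. Each intensity came with a detection p-value in the deposited table, per the file headers, and how that p-value was computed is not stated. It did not always fall as intensity rose. On FLT3-ITD replicate 1 a probe of Epor at 108.8 had a detection p of 3.48e-08, and a brighter probe of Bcl2l1, at 115.2, had 0.00175. The background step below assumes that it falls, and the detection filter and lower bounds also rest on it. A second deposited table holds processed values on a log2 scale whose making is not stated. Within each array the order of those log2 values was that of the intensities (rank correlation 1), and they differed from the values computed here by at most 0.232. Their array medians were 4.79, 4.79, 4.80 and 4.79, so they were taken as background-corrected log2 values scaled between arrays and used only as an alternative.

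Intensities were background-corrected with the normexp model in limma 3.58.1 (R 4.3.3, with statmod 1.5.0), using background moments recovered from the detection p-values and an offset of 16, then transformed to log2 and quantile-normalized. Median raw intensity was 103.1 and 105.9 on the FLT3-ITD arrays and 107.9 and 103.7 on the pMIG arrays, against an estimated background of 94.7 to 97.9. Between 51.5% and 53.5% of probes had a detection p under 0.05 on each array. Probes were kept where that held on at least 2 of the 4 arrays, which left 14178. Gene names came from the platform annotation supplied with the data. In it 24279 probes had 1 gene symbol, 0 had several and 2233 were not listed with a gene. Matching gene identifiers to the reference gene table (GRCm38.p6) changed 0 symbols. The probe with the highest mean signal over all arrays stood for its gene, chosen without regard to group, and 9948 genes were tested. Of these, 2408 had more than 1 probe passing the filter. Where every probe of a gene was below detection on all arrays of a group, the difference is given as a lower bound. That bound is the other group's mean against, per array, the higher of the lowest detected signal and the probe's own. Setting such genes to their bounds moved the median of no list (largest shift 0). The number of arrays limits the precision.

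The groups were compared with limma's linear model and empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. An exact test of 2 against 2 arrays cannot go below p = 0.333, so each call rests on the spread that the model shares between genes. Before the data were examined, 27 gene lists covering signalling pathways, blood lineages and quality markers were fixed. They hold 724 distinct genes, 82 of them with no probe listed under that name, among them Kit and Ripk1. Lists were tested with limma's camera on the moderated statistics, with a preset correlation between genes of 0.01 and adjustment over the 27 lists. The alternative test fry asks whether a list's genes move, on balance, one way against no change, and does not compare them with other genes. Counts of passing members are given over all genes tested and adjusted over the list alone. Genes were named by a rule fixed at the same time. It takes the 12 largest rises and the 12 largest falls past the threshold with the groups apart, with open places filled by the genes of largest moderated statistic and symbols that only number a gene model left out. It adds 14 genes fixed in advance, up to 4 members of each list with the smallest adjusted p, and Actb and Gapdh.

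The same steps were tested on 20 simulated sets of 4 arrays with known changes, with 10982 to 11171 genes in each. The model recovered 14.6% of 2-fold and 67.9% of 4-fold changes, and 2.73% of its calls were false. With a variance trend it recovered 68.9% and 83.1%, and 5.98% of calls were false. With the trend the model shared spread between genes less strongly in simulation than in the data (prior degrees of freedom 11.8 against 23.4). These shares therefore need not hold for the trend calls in the data. The list given a shift was found in 20 of 20 sets, and 3 of 520 tests of other lists passed. Noise was drawn separately for each probe, so simulated genes were not correlated. These list results therefore do not measure false list calls where genes vary together. Changes were underestimated, with a median error of -0.17 on the log2 scale. Alternatives covered background correction, offset, scaling between arrays, the deposited processed values, filters, variance models, the summary of probes, thresholds, list tests, the replicate number as a block and leaving out each array. Same-numbered samples did not deviate together (correlation of deviations across genes -0.018).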

Results

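The study profiled total RNA from lineage-negative mouse bone marrow cells after 48 h of FLT3-ITD signalling, with cells carrying the empty vector pMIG as the control. There were 2 arrays per group. Each array read 26512 probes, of which 13760 and 13894 were detected on the FLT3-ITD arrays and 14176 and 13646 on the pMIG arrays. Replicates of a group correlated across genes at r = 0.992 and 0.991, and arrays of different groups at 0.985 to 0.986, where genes are not independent replicates. The median absolute difference between replicates was 0.155 and 0.159 on the log2 scale, against 0.218 to 0.229 between groups.

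The series design asks which transcripts differ after 48 h of FLT3-ITD signalling. Among the genes with the largest rises were those of several protease inhibitors, a cytokine and members of the Speer family. Timp1, an inhibitor of matrix metalloproteinases (probe ILMN_2769918), rose 15.3-fold, from 6.23 ± 0.07 to 10.17 ± 0.14 (log2 signal, SD, n = 2). Il1b, which encodes the cytokine interleukin-1β (probe ILMN_2777498), rose 4.83-fold, from 7.23 ± 0.05 to 9.50 ± 0.03. Serpinb2, a serine protease inhibitor, rose 6.20-fold. Without background correction the log2 differences of Timp1 and Serpinb2 were smaller, 2.98 and 1.45, against 3.94 and 2.63. Of the 9948 genes tested, 19 passed an adjusted p of 0.05 in limma, with 17 higher and 2 lower in FLT3-ITD, and all 19 had both FLT3-ITD arrays beyond both pMIG arrays. Of all genes tested 50.6% were apart in this way, against 33.3% by chance, and 1790 had an unadjusted p under 0.05, against 497.4 by chance.

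Stefins, a family of cysteine protease inhibitors whose genes lie close together on chromosome 16, made up 5 of the 17. Stfa2 rose 9.69-fold (log2 difference 3.28, SE 0.12, adjusted p = 0.00691) and its second probe differed by 3.80. Csta3 rose by 3.93 on the log2 scale, Stfa1 by 2.38, Cstdc4 by 2.33 and Csta2 by 2.13. Csta3 was dim in pMIG and differed by 2.39 without background correction, close to 2.32 for Stfa1 and 2.28 for Cstdc4. The probes of Stfa3 and Csta1 were not detected on any array. Speer3 and Speer1, members of a family of closely related genes on chromosome 5, also rose. Speer3 was detected on 1 of 2 pMIG arrays and read 4.09 higher (adjusted p = 0.0074), or 2.15 higher without background correction, sizes that depend on a pMIG signal near the floor, and its second probe was not detected on any array and differed by -0.01. Speer1 was below detection on both pMIG arrays and was at least 10.6-fold higher in FLT3-ITD (log2 difference 1.64 without background correction), as read by 1 of its probes, and its second probe was also below detection in pMIG and detected on both FLT3-ITD arrays. Col18a1, a collagen gene, rose by 2.22 on its brightest probe. A second probe, detected on all 4 arrays but near background, differed by 0.45, and with the mean of the probes the difference was 1.34 and did not pass (adjusted p = 0.0877). Klrd1, a lectin-like receptor of natural killer cells, rose by 1.90, or by 1.02 without background correction.

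Both genes that fell are expressed in platelets and their precursors. Alox12, the platelet 12-lipoxygenase, fell by 1.84 on the log2 scale (SE 0.13, adjusted p = 0.0439), with a difference of -0.77 without background correction and its second probe near background. Treml1, a receptor stored in platelet granules, fell by 1.40 (SE 0.10, adjusted p = 0.0473). Both calls were lost with no filter on dim probes (adjusted p = 0.0652 for each) and with the replicate number as a block (adjusted p = 0.132 and 0.178), and that of Treml1 with a robust fit alone, chosen after seeing the data (adjusted p = 0.0531). The next genes by moderated statistic did not pass. Among them Serpina3b differed by -1.47 and Cldn11 by -1.21 (adjusted p = 0.0506 for both), Gnaz by -1.11, Ube2t by -1.10, Rimkla by -0.93 and Shisa2 by -0.95. Sucnr1 was below detection on both FLT3-ITD arrays and at least 2.09-fold lower. Without background correction the differences of Serpina3b, Cd200r3, Gnaz and Ube2t were -0.52, -0.53, -0.51 and -0.48, that of Sucnr1 was -0.34 and those of Rimkla and Shisa2 were -0.28. Igfbp7 differed by -1.23, with its second probe not detected on any array, Vwf by -1.09 and Cd200r3 by -1.19.

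**Figure D1:**
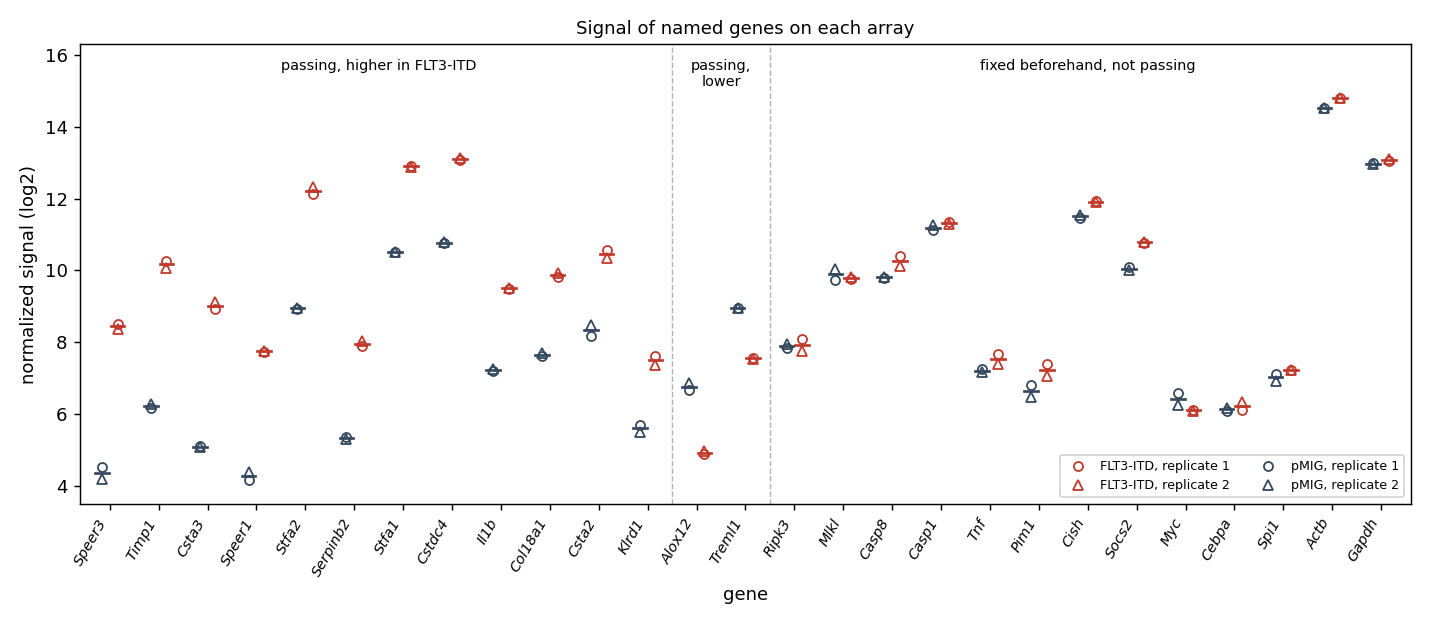
Normalized log2 signal (vertical axis) of the named genes that passed and the tested genes fixed in advance (horizontal axis) on each of the 4 arrays, with FLT3-ITD in red, pMIG in dark blue, circles for replicate 1, triangles for replicate 2 and short lines for group means. The 12 genes at the left passed and were higher in FLT3-ITD, the next 2 passed and were lower, and the rest, fixed in advance, did not pass, with Ripk3 at 7.92 in FLT3-ITD and 7.89 in pMIG.

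The count of passing genes depended on the processing. With a variance trend and robust fit, planned beforehand, 1040 genes passed, 515 higher and 525 lower. With a variance trend alone, chosen after seeing the data, 1018 passed, 504 higher and 514 lower. Without background correction 896 passed, 456 higher and 440 lower. Each of these sets included all 19. With the replicate number as a block 6 genes passed, and among the rises named above the calls of Il1b, Serpinb2, Stfa1, Cstdc4, Csta2, Col18a1 and Klrd1 were lost. With no filter on dim probes 11 genes passed, and among the rises named above the calls of Csta2 and Klrd1 were lost. Those 2 calls were also lost in limma with a robust fit alone, chosen after seeing the data (adjusted p = 0.0531 and 0.0532). With any 1 of the 4 arrays left out (FLT3-ITD replicate 1 or 2, pMIG replicate 1 or 2), 0 genes passed in limma, with 1155, 1225, 1338 and 1105 at an unadjusted p under 0.05.

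Inflammatory gene lists were shifted upward, beside upward shifts of dendritic and B lymphoid markers (medians 0.51 and 0.42). In the list of cytokines and growth factors, 1 of 29 tested members passed over all genes, and 10 were higher and 1 lower adjusted over the list alone (camera adjusted p = 7.4e-08, adjusted p = 0.21 with an estimated correlation). Il1b led it, and Ccl4, a chemokine, differed by 1.36. Il1a was detected on 1 of 2 pMIG arrays and differed by 1.35, or by 0.45 without background correction. Ifng was below detection on both pMIG arrays and at least 4.84-fold higher in FLT3-ITD, without passing over all genes (adjusted p = 0.0506), and differed by 0.95 on the log2 scale without background correction. NF-κB target genes were shifted upward (camera adjusted p = 7.4e-08, adjusted p = 0.21 with an estimated correlation), with 1 of 25 passing over all genes and 9 higher and 1 lower adjusted over the list alone, among them Bcl3 at 1.29 (0.55 without background correction) and Ccl3 at 0.89. The inflammasome and interleukin-1 list was shifted upward too (camera adjusted p = 2.26e-06, adjusted p = 0.21 with an estimated correlation), with 1 of 19 members passing over all genes and 5 higher adjusted over the list alone, including the decoy receptor gene Il1r2 at 1.07. Il1b is in all 3 lists. Ccl3, Ccl4, Tnf and other genes are in both the cytokine and NF-κB lists, and Il1a and Il18 in both the cytokine and inflammasome lists. The 3 shifts are therefore not separate evidence. Interferon-stimulated genes had a median difference of 0.34 (camera adjusted p = 1e-06, adjusted p = 0.21 with an estimated correlation), with 0 of 31 passing over all genes and 8 higher adjusted over the list alone, led by Gbp2 at 0.95, Isg15 at 0.80, Usp18 at 0.68 and Irf9 at 0.70. Immediate early and heat shock genes, a list meant to track handling, were shifted as well (camera adjusted p = 0.00648, adjusted p = 0.21 with an estimated correlation), with Junb at 0.79, Zfp36 at 0.64 and Egr2 at 0.60, against -0.56 for Hspa8. That call was lost without pMIG replicate 2 (adjusted p = 0.0836), and fry gave an adjusted p of 0.0503, in a range of 0.000895 to 0.21 over its alternatives.

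Target genes of pathways downstream of FLT3 were also shifted upward. STAT5 target genes had a median difference of 0.41 (camera adjusted p = 1.12e-06, adjusted p = 0.215 with an estimated correlation), with 0 of 20 passing over all genes and 8 higher adjusted over the list alone. Among these, the feedback inhibitors Socs3, Socs2 and Cish differed by 0.97, 0.74 and 0.40, the cyclin gene Ccnd1 by 0.86 and the cytokine gene Osm by 0.49. Pim1 differed by 0.59 and by 0.02 on its second probe, and Myc by -0.32, and neither passed. ERK pathway feedback and target genes were shifted upward (camera adjusted p = 0.00043, adjusted p = 0.21 with an estimated correlation), with 0 of 15 passing over all genes and 6 higher adjusted over the list alone, among them Ccnd1 at 0.86, Phlda1 at 0.98, Etv4 at 0.73 and Egr2 at 0.60. Egr2 is also in the list meant to track handling, which moved the same way (camera adjusted p = 0.00648). The list of BCL2 family and apoptosis genes was shifted upward (camera adjusted p = 0.00977, adjusted p = 0.21 with an estimated correlation), although 0 of 21 members passed either way. Its leading members were Bcl2a1c at 0.76, Casp6 and Bcl2l1 at 0.64 and Bcl2l11 at 0.61, with a second Bcl2l11 probe at 0.09. Ccnd1, Myc and Lif are in both the STAT5 and ERK lists, and Bcl2l1 and Mcl1 in both the STAT5 and BCL2 lists. These shifts are therefore not fully separate evidence.

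Lineage markers moved in both directions. The dendritic cell and MHC class II list had the largest median difference of the 27 lists, 0.51 (camera adjusted p = 6.08e-17, adjusted p = 0.21 with an estimated correlation), with 1 of 22 members, Klrd1, passing over all genes and 12 higher adjusted over the list alone. The antigen presentation genes H2-Eb1, Cd74 and H2-Ab1 differed by 1.33, 1.32 and 1.27 (adjusted p = 0.0506 over all genes for each). The B lymphoid list had a median difference of 0.42 (camera adjusted p = 2.95e-08, adjusted p = 0.21 with an estimated correlation), with 0 of 13 passing over all genes and 7 higher adjusted over the list alone, among them the surrogate light chain genes Vpreb3 at 1.64 and Vpreb1 at 0.96, Pou2af1 at 1.45 and Blnk at 1.03 (0.82 and 0.33 without background correction). The list of mast cell, basophil and eosinophil genes was shifted downward, with a median of -0.31 (camera adjusted p = 2.34e-05, adjusted p = 0.21 with an estimated correlation), 0 of 24 passing over all genes, and 8 lower and 1 higher adjusted over the list alone. Its leading members were Cd200r3 at -1.19, the IgE receptor gene Fcer1a at -0.87, Prg3 at -0.84 and the protease gene Prss34 at -0.83.

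The megakaryocyte and platelet list was shifted downward (camera adjusted p = 0.000419, adjusted p = 0.284 with an estimated correlation), with 2 of 18 passing over all genes, Alox12 and Treml1, and 6 lower and 2 higher adjusted over the list alone. Vwf, which encodes von Willebrand factor, differed by -1.09 and Selp, which encodes P-selectin, by 0.67. Haematopoietic stem and progenitor genes were shifted downward (camera adjusted p = 0.0428, adjusted p = 0.243 with an estimated correlation), with 0 of 21 passing either way and Cd34 at -0.62, Myb at -0.56, Gfi1 at -0.55 and Angpt1 at -0.97. This call was lost without FLT3-ITD replicate 1 (adjusted p = 0.101, in a range of 0.0187 to 0.243 over its alternatives). The neutrophil list passed (camera adjusted p = 3.1e-05, adjusted p = 0.284 with an estimated correlation) with a median of only 0.05. In it Stfa2 and Stfa1 passed over all genes, 5 of 32 members were higher and 1 lower adjusted over the list alone, and Mmp9 differed by 0.92 and Cxcr2 by 1.46 (0.87 without background correction), with a second Cxcr2 probe at background. Gfi1, at -0.55, was the member lower adjusted over the list alone, and the myeloperoxidase gene Mpo and Ms4a3, named after their values were seen, differed by -0.43 and -0.39 without passing. With the variance trend, 9 members were higher and 8 lower over all genes. With ranks in place of the moderated statistic, the megakaryocyte and neutrophil calls were lost (adjusted p = 0.196, in a range of 3.05e-05 to 0.284 over the alternatives, and 0.314, in a range of 1.97e-08 to 0.314).

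**Figure D2:**
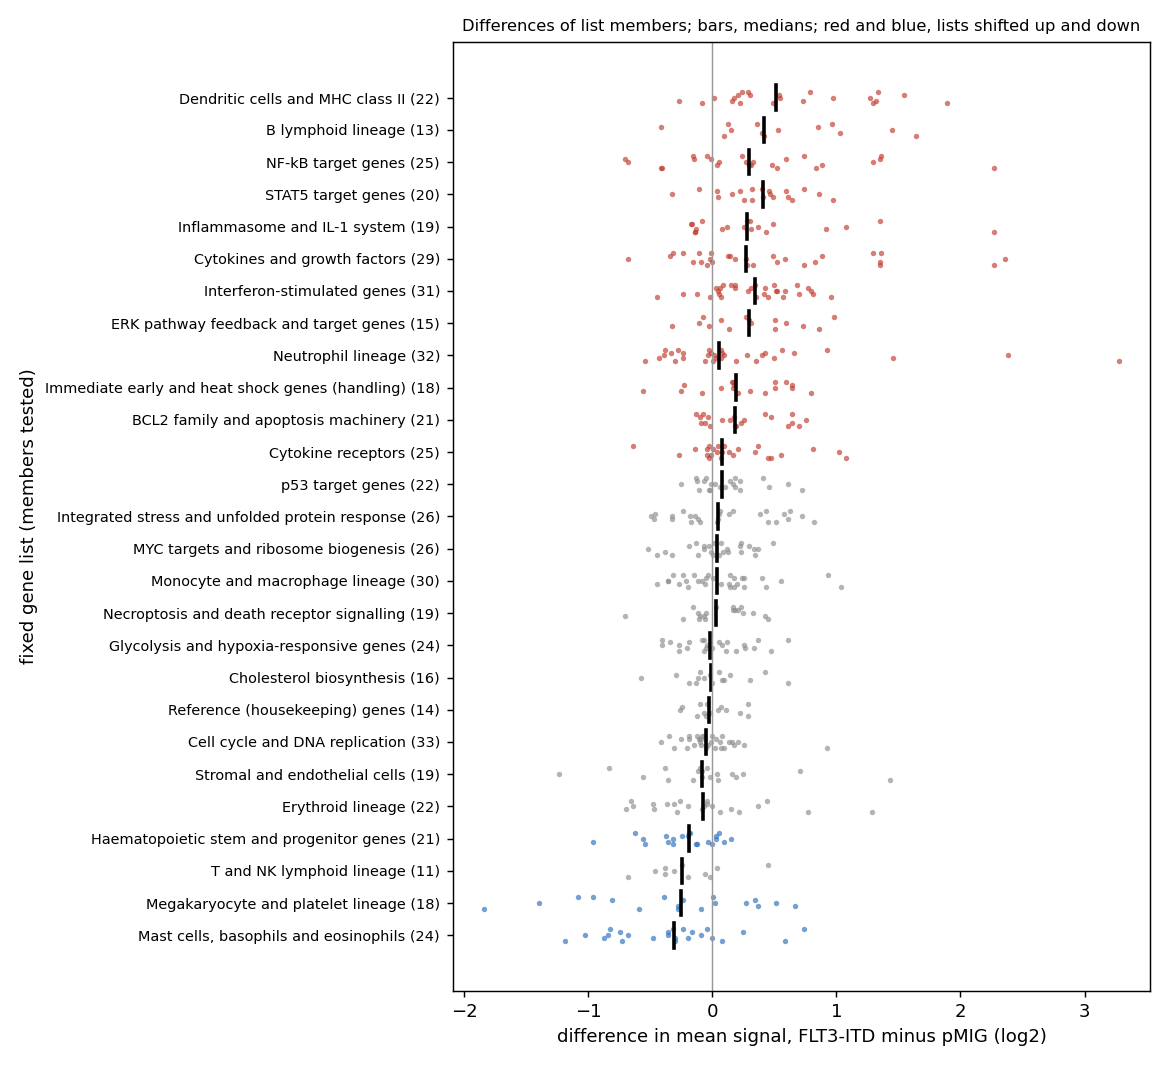
Difference in mean log2 signal, FLT3-ITD minus pMIG (horizontal axis), of each tested member (points) of the 27 fixed lists (vertical axis, members tested in brackets), with list medians as black bars and lists passing camera in red (upward) or blue (downward). Medians run from -0.31 for mast cells, basophils and eosinophils to 0.51 for dendritic cells and MHC class II.

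The series concerns RIPK3, a kinase of necroptosis, a regulated form of cell death. Every sample here was labelled WT (wild type). Ripk3 differed by 0.03 (SE 0.16) and Mlkl, which encodes the protein that permeabilises the membrane in necroptosis, by -0.10 (SE 0.15), and neither passed (adjusted p = 0.943 and 0.767). Casp8 differed by 0.44 (adjusted p = 0.228), Casp1 by 0.12 and Tnf by 0.33, and none passed. The Casp8 result depended on the processing, as it passed under 3 of 16 alternatives, and its second probe differed by 0.39. The necroptosis and death receptor list did not pass (camera adjusted p = 0.618), with 0 of 19 members passing over all genes or over the list alone, Birc2 at 0.23 (second probe -0.09) and Birc3 lower by less than the spread between replicates allows to call (adjusted p = 0.378), with 4.46 and 5.49 on the pMIG arrays. With the variance trend, chosen after seeing the data, 1 of the 19 members was higher over all genes. Ripk1 had no probe listed under its name. The Flt3 probe was not detected on any array, with raw intensities of 97.2 and 97.3 in FLT3-ITD and 96.1 and 97.2 in pMIG. Where that probe lies is not known here, so it does not check the vector. The transcription factor genes Cebpa and Spi1, which direct myeloid differentiation, differed by 0.08 and 0.22 without passing.

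Cell cycle and MYC target lists did not pass. In the cell cycle and DNA replication list the median was -0.05 (camera adjusted p = 0.829), with 1 of 33 members higher adjusted over the list alone, Ccne1 at 0.92. Mcm6 differed by -0.41 on its brightest probe and by 0.17 and -0.13 on 2 other bright probes, Ccne2 by -0.35 and Aurka by 0.25. The MYC and ribosome biogenesis list had a median of 0.04 (camera adjusted p = 0.472, but 0.0363 with fry), with 0 of 26 passing either way and Pa2g4 at 0.49, Ppan at 0.37, Cad at 0.34 and Ddx21 at -0.38. Monocyte and macrophage genes had a median of 0.04 (camera adjusted p = 0.472), with 0 of 30 passing either way, Adam8 at 1.04, Fcgr1 at 0.93, Mrc1 at 0.56 and Gpnmb at -0.45, or -0.98 on its second probe. Reference genes had a median of -0.03 and a mean of 0.01 (camera adjusted p = 0.904). Gapdh differed by 0.11. Actb differed by 0.28 on its brightest probe and by up to 1.13 on its other probes, without passing (adjusted p = 0.268).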

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

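Apart from the list calls repeated from above, all tests in this part, and the bounds that decide them, were chosen after the results were seen. Outside the gene comparison, 1 of the 875 detected probes with no listed gene (ILMN_2690603) passed when all 14178 detected probes were fitted together. It read 11.30 in FLT3-ITD and 9.25 in pMIG, a difference of 2.05 on the log2 scale (SE 0.12, adjusted p = 0.0258 in limma, higher on both FLT3-ITD arrays), a signal in data that the comparison of genes did not use.

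The dendritic and MHC class II list and the B lymphoid list were shifted upward and the mast cell and megakaryocyte lists downward, with few members passing over all genes and the 4 calls lost with an estimated correlation (adjusted p = 0.21 to 0.284). A smaller share of the main cell type would raise the markers of all other types alike. The smallest difference in mean change between a higher and a lower list was 0.91 on the log2 scale (SE 0.23). The lists were picked because they had moved apart in these data, so that gap was fixed in advance and this explanation stays open. More dendritic cells may explain the first list in part. The 8 MHC class II genes differed by 1.10 on average and the 11 other dendritic markers detected on all arrays by 0.45, a gap of 0.65 (exact permutation p = 0.0124 across genes, which are not independent). The medians were 1.28 and 0.24. The highest of the 11 was Klrd1 at 1.90, a receptor gene of natural killer cells, which raised their mean. Markers shared with other cells or near the floor can also hide a rise, so this stays open. A narrower marker set picked after its values were seen was tried and set aside as evidence. A response to interferon-γ also stays open, as members of the interferon list that it chiefly induces, a split drawn after the values were seen, differed from the rest by -0.059 (permutation p = 0.67), and the effect of FLT3-ITD on differentiation was not tested apart from the composition of the samples.

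Probes of 5 stefin genes rose, and those of Stfa3 and Csta1 were not detected. Pick-up of the bright Cstdc4 transcript by the other probes would let no probe rise more than Cstdc4, yet the less changed Stfa2 probe rose by 0.95 more (SE 0.07). Without background correction it rose by 0.80 more and the other Stfa2 probe by 0.56 more, which argues against that source for Stfa2. All 6 probes of the cluster detected on all 4 arrays rose by over 2 on the log2 scale (Csta2 by 1.89 without background correction), so probes of the cluster sharing another stefin transcript may still account for part of the rise, which probe sequences would be needed to tell. The biological alternative, a rise of several stefin genes under FLT3-ITD, remains a hypothesis.

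Among 13 probes of the Speer family, including the numbered model 4933402N22Rik, which was singled out after its values were seen, 5 were detected on both FLT3-ITD arrays and read higher, 4 of them from below detection on both pMIG arrays, by at least 2.44-fold, and the other 8 were not detected on both FLT3-ITD arrays. A higher background on the FLT3-ITD arrays is argued against by the raw intensities, where the estimated background differed by -0.84 (SE 1.63) and the least changed of those 5 probes by 37.8 (SE 12.1). Whether 1 transcript seen by several Speer probes could give the 5 higher Speer probes cannot be told apart from a rise of several genes, because probe sequences were not used here.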

How the results depend on the processing

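The variance trend alone and the robust fit alone were added after seeing the data. The 19 genes (17 higher, 2 lower) became 71 (58, 13) with median scaling, 896 (456, 440) without background correction, 387 (242, 145) with an offset of 50, 38 (33, 5) with the deposited processed values, 11 (11, 0) with no filter on dim probes, 96 (79, 17) with a stricter filter, 41 (35, 6) with the mean of a gene's probes, 1040 (515, 525) with variance trend and robust fit, 1018 (504, 514) with the trend only, 13 (12, 1) with robust only, and 81 (68, 13) at an adjusted p under 0.1. Cyclic loess gave 21 (18, 3), and all 19 were at least 2-fold. With the replicate number as a block, 6 genes passed (6 higher, 0 lower); the numbers are not known to pair the samples. Leaving out 1 array gave 0 to 0 genes, by construction with 1 residual degree of freedom fewer and a lone array assumed to vary like the other group; 1105 to 1338 genes had an unadjusted p under 0.05. The direction of the 19 held wherever they were tested. The trend moves calls by construction, as it lets bright genes have less spread (median residual SD 0.0696 in the brightest bin of genes, 0.264 in the dimmest); the cause of the other shifts was not tested. Both other splits of the 4 arrays into 2 and 2 gave 0 genes with and without the trend, too few splits for a share under 0.05. Without background correction the fold of 20 of the 122 named genes, 7 of them passing, moved by a factor of over 1.5, all 20 to smaller differences. A gene whose own fold was under that factor could shrink without being counted, so the dependence is not confined to the 20. The 15 shifted lists became 0 with an estimated correlation between genes and 13 to 16 otherwise. That correlation was estimated from only 4 arrays, which leaves the test little power. Most of the 15 lists then shared an adjusted p of 0.21 whatever their preset result, so this loss does not rank the lists. Uncalled results that changed sign were Ripk3 (-0.14 without FLT3-ITD replicate 1, -0.040 without pMIG replicate 1; range -0.14 to 0.20 over single arrays left out), Cebpa (-0.034 without FLT3-ITD replicate 2, to 0.19), Mlkl (0.055 without pMIG replicate 2, from -0.25) and, as a list's mean moderated statistic less that of other genes, reference genes (-0.00269 with no filter, -0.037 with the mean of probes), glycolysis (-0.24 without FLT3-ITD replicate 1, -0.093 without pMIG replicate 1, to 0.32), cell cycle (0.033 without FLT3-ITD replicate 2, 0.00565 without pMIG replicate 1, from -0.29) and cholesterol (-0.11 without pMIG replicate 1, to 0.29); the cause was not tested. Slide as a block was not run, as the tables give no slide. Signals near background limit dim genes.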

Other observations

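Several lists not described so far held members that stood apart. Cytokine receptors passed camera (adjusted p = 0.0242, adjusted p = 0.347 with an estimated correlation), with 0 of 25 passing over all genes and 4 higher and 1 lower adjusted over the list alone. Il1r2 differed by 1.07, Csf2rb, the shared receptor subunit for GM-CSF and interleukin-3, by 1.02, Il10ra by 0.55 and Epor, the erythropoietin receptor gene, by -0.64. That call was lost without FLT3-ITD replicate 2 (adjusted p = 0.173), without pMIG replicate 1 (adjusted p = 0.0659) and with the mean of probes (adjusted p = 0.0546), and fry gave an adjusted p of 0.108, in a range of 0.00415 to 0.347 over its alternatives. The integrated stress and unfolded protein response list did not pass (camera adjusted p = 0.125), though 7 of 26 members were higher and 1 lower adjusted over the list alone, with Slc7a11 at 0.82, Sesn2 at 0.72, Nupr1 at 0.63 and Vldlr at 0.61. Erythroid genes did not pass (camera adjusted p = 0.472), with 1 of 22 higher and 3 lower adjusted over the list alone. Hba-a1, a globin gene, differed by 1.29, while Epor, Ank1 and Aqp1 were lower, at -0.64, at least 1.51-fold lower and -0.70, with other Aqp1 probes at -0.36 and 0.07.

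Stromal and endothelial genes did not pass (camera adjusted p = 0.562), with 2 of 19 higher and 3 lower adjusted over the list alone, among them Col5a1 at 1.43, Igfbp7 at -1.23, Serpinf1 at -0.83 and Vcam1 at -0.56. T and NK lymphoid genes had a median of -0.24 (camera adjusted p = 0.0791), with 1 of 11 lower adjusted over the list alone, Ccl5 at -0.68. The list passed without FLT3-ITD replicate 1 (adjusted p = 0.0329), without pMIG replicate 1 (0.0245), with a stricter filter (0.00501) and with a variance trend only, chosen after seeing the data (0.0456), in a range up to 0.417 over its alternatives. Nkg7 differed by -0.47, Thy1 by -0.38, and Il2rb was below detection on both pMIG arrays and at least 1.36-fold higher in FLT3-ITD. That bound equals its fitted fold with background correction, and its log2 difference was as low as 0.13 over the alternatives. p53 target genes (camera adjusted p = 0.102), glycolysis and hypoxia genes (0.764) and cholesterol biosynthesis genes (0.829) did not pass, with 0 of 22, 0 of 24 and 0 of 16 members passing either way. The p53 list passed without FLT3-ITD replicate 1 (adjusted p = 0.0246), and fry gave an adjusted p of 0.0363, in a range up to 0.285 over its alternatives. In the glycolysis and cholesterol lists the median was below 0 and the mean above 0. The passing genes outside the naming rule, named after their values were seen, were Adam23 at 1.59, Jaml at 1.59, Mzb1 at 1.53, the numbered model 4933402N22Rik, at least 9.57-fold higher, and Apoa1, which was below detection on both pMIG arrays and at least 3.06-fold higher in FLT3-ITD. Of all 19 passing genes, 11 kept their calls with no filter on dim probes and 6 with the replicate number as a block. Most of the genes outside the naming rule lost theirs under each. Raw intensities of 4933402N22Rik were 261.1 and 274.7 in FLT3-ITD and 90.8 and 89.3 in pMIG, so its fold depends on a pMIG signal near the floor.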
